A study of Homo sapiens with 4 samples.

How the data were processed

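RNA-seq was carried out on SEM cells, a human B-cell precursor acute lymphoblastic leukemia line carrying a KMT2A::AFF1 fusion. Per the labels' protocols, one stable line had received a lentiviral vector for GFP only and the other a vector for CD9 with GFP, both under puromycin selection. Each line was exposed to DMSO or to 1 µM dexamethasone, a synthetic glucocorticoid, for 8 h. This gave 4 groups with 1 library each, made with a strand-specific NEBNext Ultra kit from total RNA, per the labels' protocols. How ribosomal RNA was removed, and whether reads were counted by strand, is not given in the sources used here.

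STAR and Partek 10 and the hg38 build are listed in the submitters' processing notes, with no role or order. The deposited matrix held 20073 genes with their Ensembl identifiers, symbols and positions, of which 13450 were protein-coding. Its values, as deposited by the authors, were CPM (reads scaled to a fixed total in each library) with a constant of 0.001 added, although the table was presented as counts. Every column summed to the same total, and the low values were spaced by what 1 read was worth. That spacing was 0.0699 CPM in the GFP DMSO library, 0.0706 CPM in the GFP dexamethasone library, 0.0676 CPM in the CD9 DMSO library and 0.0820 CPM in the CD9 dexamethasone library. The matching totals were 14307216, 14173459, 14794169 and 12197353 reads assigned to genes. Between 83.2% and 84.7% of the values in a library were whole multiples of 1 read within 0.02 reads. The remainder were fractional, and genes with a fractional value in any library held 54.7% of the reads, so that reads shared between genes had been divided by estimation. A fractional value in at least 2 libraries was therefore used to mark genes with shared reads, and their levels are uncertain.

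A count model had been chosen before the data were examined. Because the values were CPM with divided reads, limma 3.58.1 in R 4.3.3 was used in its place, on log2 of CPM divided by a TMM factor plus a pseudocount of 0.145 CPM, which equals 2 reads. Fold changes are on this scale, which understates changes of low genes. TMM factors, computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, were 0.998, 0.989, 1.004 and 1.009 in the order above. Genes with at least 1 CPM in at least 2 libraries were tested, which left 14592 genes, 11675 of them protein-coding. The model had a term for line and a term for treatment, with a variance trend and robust empirical Bayes moderation, and 1 residual degree of freedom. Its residual is the difference between the dexamethasone responses of the lines, but the median prior degrees of freedom were 95.64, so for most genes the variance in the test comes mainly from the trend over all genes and a gene can pass although that difference exceeds its mean change. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Since nothing in the labels points to repeated cultures, the p-values measure only the spread between these libraries, which may be technical, and a line effect cannot be parted from chance differences between stable lines.

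A test of the response difference between lines has 0 residual degrees of freedom and was not made. That difference, and the ratios of single libraries, are given without p-values. Their 95% intervals cover counting error only, on reads that are not independent molecules. A rule of size was used instead: an absolute log2 ratio of at least 1, an interval that excludes 0 and at least 100 reads in a library. The slope of the response in the CD9 line on that in the GFP line was the major axis over genes that passed for treatment. An upper limit of 3 reads, about 0.203 to 0.246 CPM, was taken for a library with no reads of a gene.

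Before the data were examined, 30 gene lists and the rule for named genes were fixed. For treatment and for line, the rule took the 10 highest and 10 lowest genes that passed the test, moved the same way by at least 2-fold in both single comparisons and had 100 reads in a library. For the response difference it took the 10 highest and 10 lowest past the rule of size. CD9, NR3C1, up to 4 members of a list with the largest change and members moving against their list were added, and genes with clone names only were skipped. Only 2 genes, both with clone names, met the rule for line, so the genes named there were chosen after their values were seen, as were FKBP5, TSC22D3, DDIT4, VPREB1 and the glucocorticoid-induced genes named for their response difference. A list's percentile is the place of its median among 10000 random lists of the same size matched on mean expression, and describes these libraries only. List counts adjusted over the list alone use the same p-values with adjustment within the list.

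The test was run on simulated data with the real means and depths. At a biological coefficient of variation of 0.05 for the treatment comparison over 14531 genes, 60.0% of genes changed by a log2 of 0.5 were called, 92.0% at 1, 100.0% at 2 and 79.6% at -1, with 2 false calls. At a coefficient of 0.10, over 14538 genes, these were 40.0%, 96.0%, 100.0% and 75.5%, with 11 false calls. The simulated line comparison, which held no change, gave 0 false calls at both settings. The simulated data held equal responses in both lines, no divided reads and no trend with GC content. These counts therefore do not bound the false calls in the real libraries.

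Alternatives covered median-of-ratios scaling, total-only scaling, other filters, limma-voom on estimated reads, a model without the second factor, each library left out, other pseudocounts and other limits of the size rule. Added after seeing the data were the pseudocounts in the tests, moderation without the robust option, restriction of the slope to deep or one-directional genes, restriction to genes with whole reads, and removal of a smooth trend on GC content and transcript length. GC content and length came from the GENCODE reference through gene identifiers, and 99.0% of the tested genes had a value. Smoothing used statsmodels 0.14.6, intervals scipy 1.17.1 and plots matplotlib 3.10.9.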

Results

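Transcript levels were measured by RNA-seq in 4 libraries of SEM leukemia cells. A control line expressing GFP and a line overexpressing CD9, a tetraspanin of the cell surface, were each treated with DMSO or with 1 µM dexamethasone for 8 h. The stated aim was to find genes that differ between CD9-low and CD9-overexpressing cells after dexamethasone. Depth was 14307216 reads assigned to genes in the GFP DMSO library, 14173459 in the GFP dexamethasone library, 14794169 in the CD9 DMSO library and 12197353 in the CD9 dexamethasone library. With 1 library per group, no value has a replicate error. All 6 pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom from 3.89 for the DMSO pair to 19.9 for GFP DMSO against CD9 dexamethasone.

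CD9 itself (ENSG00000010278, chromosome 12, 6199715 to 6238272, plus strand, hg38) was measured first. Its level was 7.49 CPM with DMSO and 6.06 CPM with dexamethasone in the GFP line, against 423 CPM and 565 CPM in the CD9 line, and its reads were fractional in 2 libraries, the mark used here for shared reads. The fitted difference between lines was a log2 of 6.15 with a standard error of 0.26, or 71.0-fold. The single comparisons gave 5.79 with DMSO and 6.51 with dexamethasone. Its adjusted p in limma was 0.0591, above the threshold, and 2.27e-37 without the robust option. Across all alternatives CD9 passed, with adjusted p of at most 0.0446. Within the CD9 line, the dexamethasone library was higher by a log2 of 0.42 (95% counting interval 0.37 to 0.47), and in the GFP line the ratio was -0.30 (-0.71 to 0.11).

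NR3C1, the glucocorticoid receptor gene (ENSG00000113580, chromosome 5, 143277931 to 143435513, minus strand), rose with dexamethasone across lines by a log2 of 0.23 (standard error 0.05, limma adjusted p = 0.000292). That call was lost without the line term (adjusted p = 0.0592) and on leaving out 1 library (adjusted p up to 0.543). Its levels were 252 CPM and 293 CPM in the GFP line and 267 CPM and 318 CPM in the CD9 line, and part of its reads were shared with other genes. Between lines NR3C1 differed by a log2 of 0.10 (adjusted p = 0.380), which did not pass. The NR3C1 response to dexamethasone differed between lines by 0.04, with a counting interval of -0.05 to 0.13.

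**Figure D1:**
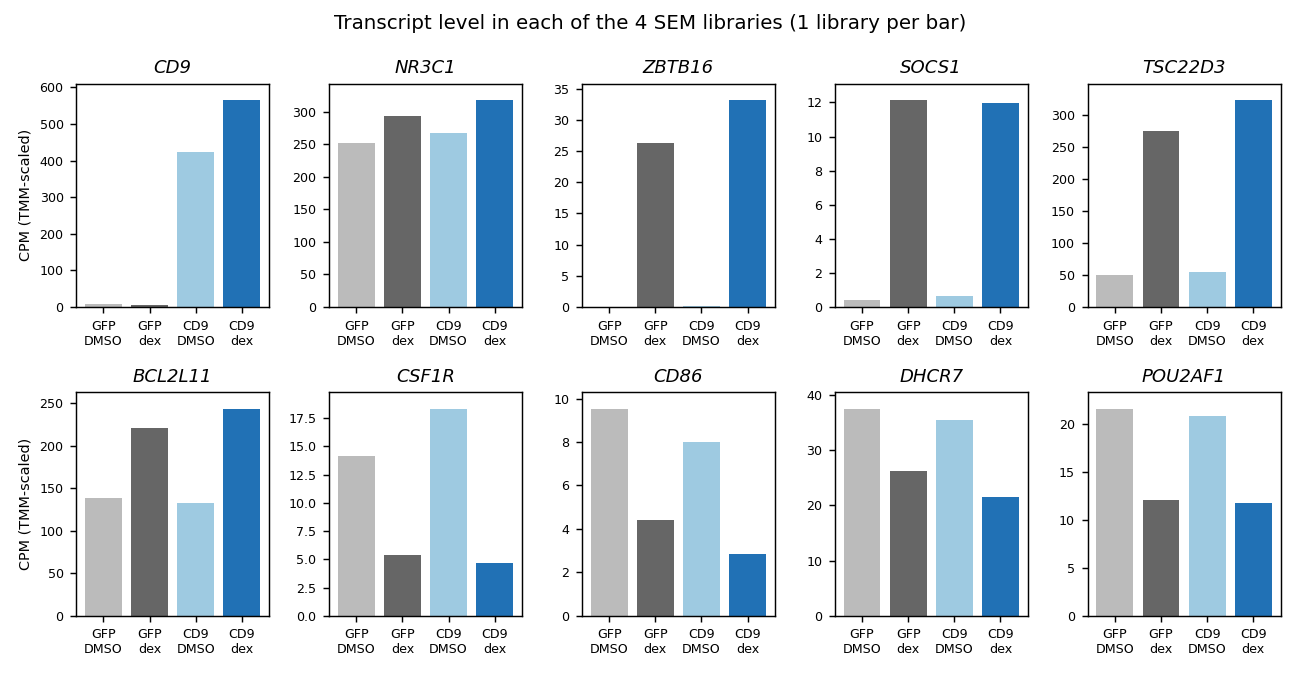
Bars give the TMM-scaled level in CPM of 10 genes in each of the 4 libraries (GFP or CD9 line, DMSO or dexamethasone), on linear axes starting at 0, with 1 library per bar and no error bar. CD9 stands at 423 and 565 CPM in the CD9 line against 7.49 and 6.06 CPM in the GFP line, while TSC22D3 rises from 50.1 to 275 CPM in the GFP line and from 54.8 to 322 CPM in the CD9 line.

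Among genes named by rule, the highest dexamethasone ratios were those of ZBTB16, STAB1, ARNT2 and SOCS1. ZBTB16, a zinc-finger transcription factor (ENSG00000109906, chromosome 11, 114059711 to 114256766), had 0 reads in the GFP DMSO library and 0.135 CPM in the CD9 DMSO library, against 26.3 CPM and 33.2 CPM with dexamethasone. ZBTB16 was at least 125-fold higher in the GFP line, taking 3 reads as the floor, and its log2 ratio in the CD9 line was 6.90 (counting interval 5.48 to 8.32; limma adjusted p = 9.31e-38 across lines). STAB1, a scavenger receptor (chromosome 3, 52495338 to 52524496), rose from 0.420 to 26.0 CPM in the GFP line and from 0.269 to 34.4 CPM in the CD9 line. SOCS1, an inhibitor of cytokine signalling through JAK and STAT proteins (chromosome 16, 11254408 to 11256205), rose 17.9-fold. SMIM3, a small membrane protein, rose by a log2 of 4.09, with levels of 4.13 and 3.97 CPM in DMSO against 69.1 and 73.2 CPM. ARNT2, a transcription factor of the bHLH-PAS family, rose by a log2 of 4.21 (standard error 0.40). The rise was 8.87-fold for NDRG2, 8.84-fold for THSD4, 7.84-fold for ISG20, an exonuclease, 6.93-fold for LCN10, a lipocalin with shared reads, and 6.70-fold for GSDME, a gasdermin. Among the 10 genes with the highest ratios, adjusted p in limma was at most 2.83e-15 (THSD4).

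The lowest ratios among genes named by rule included ANGPT4, CSF1R and VSIR. ANGPT4, an angiopoietin (chromosome 20, 869900 to 916335), fell to 0.272 of its DMSO level, with log2 ratios of -1.80 in the GFP line and -1.956 in the CD9 line. CSF1R, the receptor of macrophage colony-stimulating factor (chromosome 5, 150053291 to 150113373), fell to 0.320 of its level (log2 -1.64, standard error 0.18, limma adjusted p = 3.28e-13). VSIR, an immune checkpoint protein, fell to 0.358 and CD86, a costimulatory ligand, to 0.416. GNA15, a G protein subunit, fell to 0.411, RTN4R, the Nogo receptor, to 0.416, HTRA3, a serine protease, to 0.431, and GPRC5C, an orphan receptor, to 0.436. PDZD7, a PDZ-domain protein, fell to 0.390. FAM156B, which shares reads with other genes in all 4 libraries, fell to 0.318, and lost its call without the line term.

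In all, 2062 of 14592 genes passed for dexamethasone in limma, 923 higher and 1139 lower, and all 2062 had the same direction in both lines, which choosing genes by their mean change favours. Changes of at least 2-fold were seen for 200 of the genes that rose and 64 of those that fell. Median GC content was 54.2% for the genes that fell, 45.3% for those that rose and 47.6% for all. The single comparisons put 107 genes higher and 23 lower past the rule of size in the GFP line, and 115 and 43 in the CD9 line, of which 93 and 9 were common. Without the line term 747 genes passed, and leaving out single libraries gave 524 without GFP DMSO, 563 without CD9 DMSO, 948 without CD9 dexamethasone and 2488 without GFP dexamethasone. Of the 1139 lower genes, 925 passed again once a trend on GC content and length, chosen after seeing the data, was removed, and 855 of the 923 higher genes did.

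Of the fixed list of glucocorticoid-induced genes, 30 of 44 measured members rose and 5 fell, as they did when adjusted over the list alone. The median log2 ratio was 0.73, at the 100th percentile of matched random lists. Beyond ZBTB16, SOCS1 and ISG20, CD163, a scavenger receptor of low level here, went from 0.0700 to 1.14 CPM in the GFP line and from 0.0673 to 2.36 CPM in the CD9 line. FKBP5, a co-chaperone of the receptor with shared reads, rose 5.88-fold, TSC22D3, encoding the leucine zipper protein GILZ, 5.67-fold and DDIT4, an inhibitor of mTORC1 signalling, 5.41-fold. The 5 members that fell were TNFAIP3 (log2 -0.92), an inhibitor of NF-κB signalling, RGS2 (-0.61), CEBPB (-0.46), TBC1D8 (-0.23) and TLE3 (-0.22). Without the line term RGS2, TBC1D8 and TLE3 no longer passed.

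Among 36 members of the receptor machinery (chaperones, cofactors and regulators of the receptor), 12 fell and 1, NR3C1, rose (14 and 2 adjusted over the list alone), the call of NR3C1 being lost without the line term. HSPA1A, a heat shock protein with shared reads, fell by 0.60 on the log2 scale, NLRP3, an inflammasome sensor, by 0.59, DNAJA1 by 0.44 and HSP90AA1, with shared reads, by 0.31. Of 9 heat stress genes, 6 fell and none rose (7 and 0 adjusted over the list alone), with HSPB1 at a log2 of -0.86. The heat stress list shares members with the receptor machinery, HSP90AA1 among them, so their results are not separate. HSPB1 lost its call without the line term. In the BCL2 family, 4 of 16 fell and 1 rose (5 and 1 adjusted over the list alone). BCL2L11, encoding the pro-apoptotic protein BIM, rose 1.71-fold, from 138 to 221 CPM in the GFP line and from 133 to 244 CPM in the CD9 line, with part of its reads shared. BMF fell to 0.585 of its level, BID to 0.704 and BCL2L12 to 0.737, while BCL2, the anti-apoptotic founder of the family, fell by 0.18 on the log2 scale. BCL2 and BCL2L12 did not pass without the line term.

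Cholesterol synthesis transcripts fell together: 15 of 24 members fell and none rose (16 and 0 adjusted over the list alone), with a median log2 ratio of -0.27 at the 0th percentile. DHCR7, the last enzyme of one branch of the pathway, fell by 0.62, SQLE, squalene epoxidase, by 0.45 and HMGCS1, with shared reads, by 0.42. Of 26 interferon response genes 8 fell and none rose (11 and 0 adjusted over the list alone). XAF1, a pro-apoptotic interferon target, fell by 1.02, MX2, an antiviral GTPase, by 0.75, OAS1 by 0.67 and BST2, tetherin, by 0.55. MX2 and OAS1 did not pass without the line term, and OAS1 also not with a filter of 5 CPM. In the NF-κB list 5 of 17 fell and 1 rose (5 and 1 adjusted over the list alone). NFKBIA, the inhibitor IκBα, rose 2.32-fold, while TNFAIP3 fell as above and RELB had a log2 ratio of -0.53, which did not pass without a filter or after removal of the GC trend.

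Adhesion and migration genes went both ways, with 10 of 35 lower and 5 higher (11 and 6 adjusted over the list alone). CXCR4, a chemokine receptor with shared reads, rose 2.78-fold and RHOH, a small GTPase of blood cells, 1.79-fold, while the integrin genes ITGAL and ITGB7 fell to 0.499 and 0.547. EZR rose by a log2 of 0.59, with shared reads, CD58 by 0.35 and CD44 by 0.26, and the last pair did not pass without the line term. Among B-cell precursor genes 13 of 40 fell and 5 rose (16 and 5 adjusted over the list alone). POU2AF1, a B-cell coactivator, fell to 0.563 and IL7R, the interleukin-7 receptor, to 0.617, and TCF4 fell by a log2 of 0.62, lost without the line term. CD24 rose by a log2 of 1.09, BLK, a kinase of B cells, by 0.61, IRF4 by 0.48, IKZF1, with shared reads, by 0.48 and CD72 by 0.33, the last lost without the line term. Of 32 genes bound or raised in KMT2A-rearranged leukemia 6 rose and 4 fell (7 and 5 adjusted over the list alone). ELL2 rose 2.45-fold, CSPG4 1.77-fold and FLT3 1.41-fold, the first and last with shared reads. PARP8 fell by 0.41, DOT1L by 0.22 and BCL2 by 0.18, all lost without the line term, as was EPHA7, whose log2 ratio was -0.95 with a limma adjusted p of 0.0495.

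Tetraspanins, the family of CD9, had 2 of 15 members higher and 1 lower (2 and 1 adjusted over the list alone). CD53 rose 1.71-fold and TSPAN14 1.45-fold, while CD37 had a log2 ratio of -0.54, lost after removal of the GC trend. For CD37 the ratio was -0.13 in the GFP line and -0.95 in the CD9 line. Of 14 genes for CD9 partner proteins 3 fell and 2 rose (3 and 2 adjusted over the list alone): HBEGF, a growth factor precursor, fell to 0.541, ITGA6 by a log2 of 0.50 and ITGA4, with shared reads, by 0.42, while ADAM17 rose by 0.45 and CD44 by 0.26. ITGA6 and CD44 did not pass without the line term. In glycolysis 7 of 25 fell and 2 rose (11 and 3 adjusted over the list alone), with PFKFB4 at a log2 of -0.92, SLC2A3, a glucose transporter with shared reads, at -0.51, PFKFB3 at -0.43, HK2, with shared reads, at 0.36 and SLC2A1 at 0.31. PFKFB4 was lost without the line term.

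**Figure D2:**
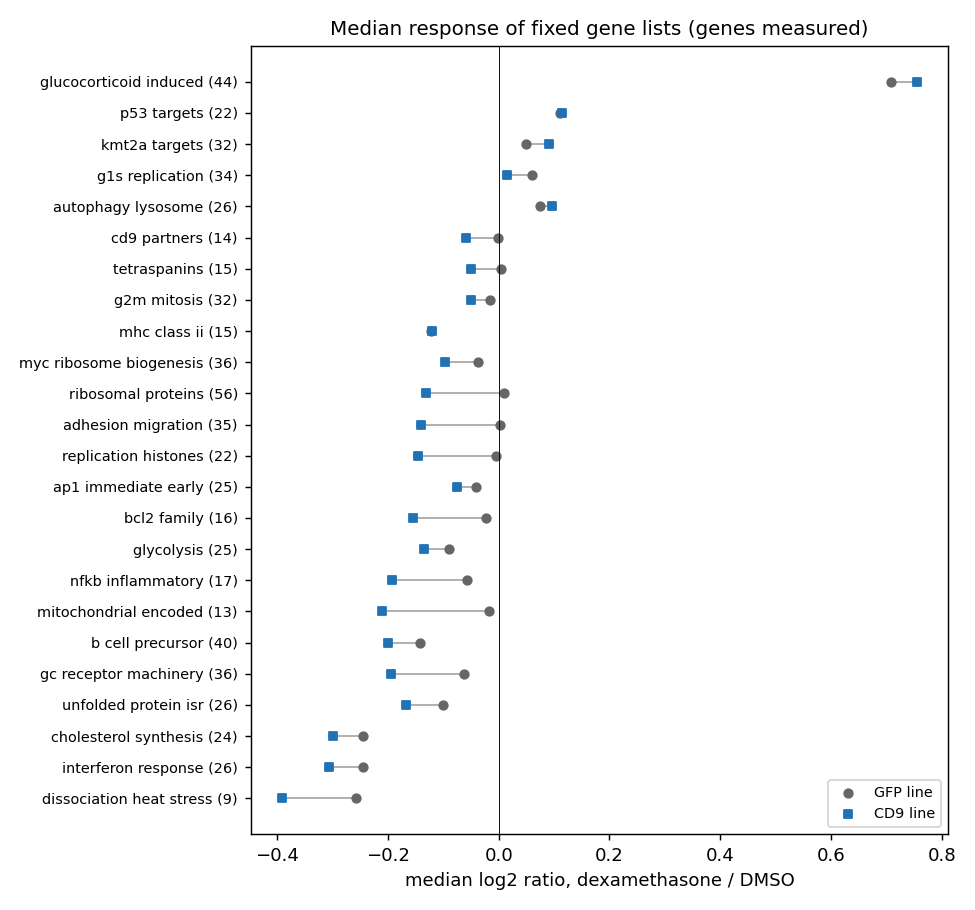
Points give the median log2 ratio of dexamethasone to DMSO over the measured members of each fixed list with 9 or more members (number in brackets), as circles for the GFP line and squares for the CD9 line, with 1 library per condition and no error bar. The glucocorticoid-induced list lies at 0.709 and 0.755, and the cholesterol synthesis list at -0.25 and -0.30.

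The comparison of lines across treatments gave smaller differences. Mitochondrially encoded mRNAs were lower in the CD9 line, where 10 of 13 fell short of the GFP line and none exceeded it (11 and 0 adjusted over the list alone), with a median log2 difference of -0.39 at the 0th percentile. MT-ND5, a subunit of respiratory complex I, was at 1021 and 925 CPM in the GFP line and at 697 and 615 CPM in the CD9 line, MT-ND3 differed by a log2 of -0.53 and MT-CO1, with shared reads, by -0.51. Replication histones were lower for 8 of 22 members and higher for none (11 and 0 adjusted over the list alone), with H2BC9 at a log2 of -0.47 and H4C5 at -0.40. Of 35 adhesion genes 6 were lower and none higher (10 and 0 adjusted over the list alone). These included ITGA6, an integrin subunit that binds laminin (log2 -0.44), LGALS1, encoding galectin-1 (-0.42), RAC2, a small GTPase (-0.39), and FERMT3, kindlin-3 (-0.29). The difference of RAC2 was -0.20 in DMSO and -0.58 with dexamethasone, so it came largely from the dexamethasone libraries. For ITGA6 it was -0.55 in DMSO and -0.32 with dexamethasone.

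Other genes that differed between lines were chosen after their values were seen. PTPN14, a tyrosine phosphatase, was lower in the CD9 line (log2 -0.80, standard error 0.10, limma adjusted p = 3.90e-09), with log2 differences of -0.85 in DMSO and -0.75 with dexamethasone. CCNA1, the germline cyclin A, stood at a log2 of -0.88, S100A11 stood at -0.77, S100A10 at -0.57, ECM1, an extracellular matrix protein, at -0.64 and ZYX, the focal adhesion protein zyxin, at -0.58. CD74, the class II invariant chain with shared reads, stood at -0.48 and HLA-DPA1 at -0.32. NRP1, neuropilin-1, stood at -0.72, and this gene also rose 5.97-fold with dexamethasone across lines. Higher in the CD9 line were RHOBTB3 (log2 0.66), MYO6 (0.58), an unconventional myosin, ADGRL3 (0.51), an adhesion G protein-coupled receptor, and PFN2 (0.77), a profilin.

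In all 340 genes passed for line in limma, 81 higher and 259 lower in the CD9 line, with 10 and 9 past 2-fold. Across genes, Spearman's rank correlation of the line ratio with GC content was -0.28 with dexamethasone and -0.04 in DMSO. Once a trend on GC content and length, chosen after seeing the data, was removed, 210 of the 259 lower genes and 67 of the 81 higher genes passed again. With scaling to total reads only, 153 were higher and 269 lower, a share of 36.3% higher against 23.8%. These calls rest on the treatment term: without it only CD9 passed, and leaving out a library, which also drops that term, left 1 or 2 genes. With DMSO alone 9 genes were higher and 8 lower past the rule of size, and with dexamethasone alone 5 and 9.

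The size of the dexamethasone response in each line was compared over the 2062 genes that passed for treatment, bearing on whether CD9 changes the response. The slope of the CD9 line on the GFP line was 1.11, with an interval of 1.06 to 1.15 from resampling genes, which are not independent replicates. Genes that rose had a median log2 ratio of 0.43 in the GFP line and 0.45 in the CD9 line, and the ratio was larger in the CD9 line for 541 of 923 (58.6%). Genes that fell had medians of -0.27 and -0.405, and 853 of 1139 (74.9%) fell further in the CD9 line. Glucocorticoid-induced genes showed a median response difference of 0.01, with 25 of 44 members above 0. The response difference of NFKBIA was -0.02, of DDIT4 0.03, of FKBP5 0.06 and of TSC22D3 0.10, each with a counting interval that included 0. Of the 44 members, 4 had an interval above 0 (KLF13, TXNIP, ACSL1 and TGFBR2) and 4 below 0 (PER2, MT1X, TLE3 and IRS2), with differences from -0.52 for MT1X to 0.24 for TXNIP. For BCL2L11, with part of its reads shared, it was 0.20 (0.08 to 0.31). These counting intervals are narrower than the spread between genes. Over genes with at least 500 reads in every library the response difference had a standard deviation of 0.133, against 0.083 from counting error. Correlation across genes, which are not independent replicates, was 0.51 over all 14592 genes and 0.92 over those called. Choosing genes by their mean change over the same ratios favours the higher value, so it does not measure how alike the lines respond. Lower median responses in the CD9 line were seen for mitochondrially encoded mRNAs (-0.19, with 0 of 13 above 0), heat stress genes (-0.16, with 2 of 9 above 0), ribosomal protein mRNAs (-0.11, with 7 of 56 above 0), the receptor machinery (-0.11, with 12 of 36 above 0) and replication histones (-0.07, with 7 of 22 above 0). Intervals from resampling members, which are not independent replicates, included 0 for heat stress genes (-0.25 to 0.01) and histones (-0.19 to 0.02) and excluded it for the other lists named. They also excluded 0 for MYC and ribosome biogenesis genes (median -0.06, -0.10 to -0.0033) and mitotic genes (-0.05, -0.084 to -0.00069). The same held for myeloid, stromal and mature B-cell markers, lists of at most 4 measured members. Several other lists had medians below 0 with intervals that included 0. The median over all tested genes was itself -0.017, so an interval that excludes 0 is a weak mark. Among matched random lists, mitochondrial mRNAs lay at the 0.005th percentile, ribosomal protein mRNAs at the 0th and the receptor machinery at the 0.04th. Heat stress genes lay at the 0.81th, histones at the 1.77th, MYC and ribosome biogenesis genes at the 2.72th and mitotic genes at the 6.41th. The CD9 dexamethasone library also had a trend with GC content: across genes, Spearman's rank correlation of the dexamethasone ratio with GC was -0.28 in the CD9 line and -0.09 in the GFP line. No test of these differences was possible with 0 residual degrees of freedom.

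**Figure D3:**
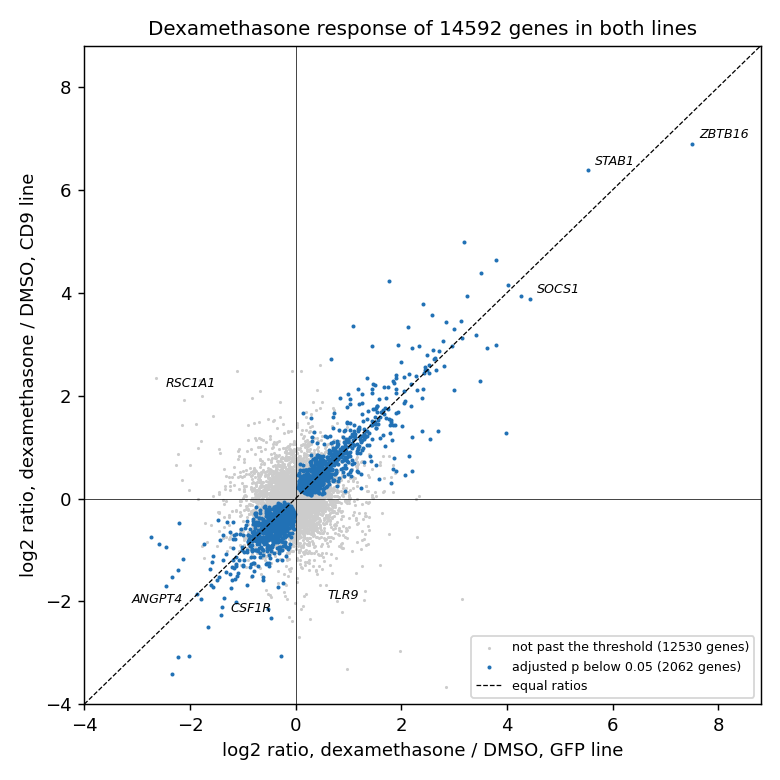
Each point is 1 of 14592 genes, placed by its log2 ratio of dexamethasone to DMSO in the GFP line (horizontal) and in the CD9 line (vertical), with the 2062 genes past the limma threshold in blue, the others in grey and equal ratios on the dashed line. Called genes follow the dashed line with a slope of 1.11, and ZBTB16 and STAB1 lie at the upper end.

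A response that differed between lines by the rule of size was found for 38 genes, 18 higher and 20 lower in the CD9 line. Of the 38, 26 (68.4%) had shared reads in at least 2 libraries, against 21.0% of all tested genes. All of RSC1A1, INO80B-WBP1, BCL2L2-PABPN1, RPL21P75, RGPD6, DUS4L-BCAP29 and SMG1P6 among the higher genes were of this kind, several of them readthrough genes, pseudogenes or near-identical copies, up to 3.78 for RSC1A1. So were TLR9, ATP5MF-PTCD1, RGPD5, TREX1, H2AC7 and AGAP5 among the lower genes, from -2.15 (TLR9) to -1.29 (AGAP5). With whole reads, the highest were ZNF75A (1.097, counting interval 0.48 to 1.71), NFKBIL1 (1.095, 0.49 to 1.71) and LILRA1 (1.031, 0.24 to 1.82), a leukocyte receptor that rose 5.50-fold across lines. The lowest were GEMIN8 (-1.57, -2.14 to -0.99), IL4R, an interleukin-4 receptor subunit (-1.37, -2.05 to -0.69), ZNF711 (-1.21, -1.73 to -0.69) and NEDD9, an adhesion scaffold protein (-1.13, -1.71 to -0.55). With a minimum of 500 reads 1 gene passed the rule, and with whole reads in at least 3 libraries 12 genes, the latter limit chosen after seeing the data.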

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

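The tests on shared reads, on GC content within each list and on RNA without a poly(A) tail were chosen only after the result was seen. The GC and length correction and the restriction to deep genes, used for the slope, were also added after seeing the data. Limits for the slope were set before those tests were run. Dixon's rule could not be used with 1 library per group.

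In 9 named genes the dexamethasone ratio went opposite ways in the lines, with both counting intervals excluding 0, and the difference was not tested. Naming genes for a large response difference in the same libraries favours opposite directions. The response difference was 3.78 for RSC1A1, 2.90 for INO80B-WBP1, 1.87 for RPL21P75 and 1.11 for DUS4L-BCAP29, all with shared reads. It was -1.85 for ATP5MF-PTCD1, which also shares reads, and -1.57 for GEMIN8, -1.37 for IL4R, -1.13 for NEDD9 and -1.10 for VPREB1, which have whole reads. IL4R went from 4.97 to 7.42 CPM in the GFP line and from 5.79 to 3.25 CPM in the CD9 line. Over all tested genes 161 met the same condition, 92 of them without shared reads in 2 or more libraries.

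The genes past the rule of size for the response difference may owe their place to shared reads. Of the 38, 68.4% had fractional reads in at least 2 libraries, against a median of 21.1% (95% range 7.89% to 34.2%) in matched random sets, so this explanation remains open for those 26. Counting error stays open for part of them: with intervals widened for all genes tested, 16 of 38 still excluded 0, and of these only GEMIN8 and VPREB1 had whole reads. VPREB1, a surrogate light chain gene of B-cell precursors, had a response difference of -1.10 (-1.54 to -0.66). A biological effect of CD9 on these genes stays open and untested.

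Mitochondrially encoded and ribosomal protein mRNAs were lower in the CD9 dexamethasone library than the other 3 libraries would give. A trend on GC content and length is argued against as the whole cause, since after its removal the median response difference was -0.20 (-0.19 before) for 13 mitochondrial genes and -0.0708 (-0.11 before) for 56 ribosomal protein genes, both at the 0th percentile of matched lists. For the receptor machinery the median went from -0.11 to -0.0391, at the 5.86th percentile, so there the trend could account for the lower values. Loss of RNA without a poly(A) tail predicts lower values for such RNAs than for mitochondrial mRNAs, most of which are polyadenylated, and it stays open. Over 27 such RNAs the median was higher than theirs by 0.113 (0.00184 to 0.203), but taken apart the interval included 0 for 22 histones (-0.01 to 0.23) and for 5 small non-coding RNAs (-0.18 to 0.18). Each of these 5 had a response difference below 0, and RN7SK, at -0.37, lay below the mitochondrial median. A change in the cells from CD9 with dexamethasone and other differences of this single library stay open, untested.

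The response was larger in the CD9 line over called genes, with a slope of 1.11, and within one direction by less, with 1.051 for genes called higher and 1.069 for genes called lower. More counting noise in the shallower library is argued against, as genes with at least 500 reads in every library gave 1.16 (resampling interval 1.14 to 1.19). The GC trend and a larger response cannot be told apart. After removal of the trend, a step added after seeing the data, the slope was 1.09, above the limit set before that test was run. Its resampling interval (1.047 to 1.13) still reached below that limit. The median difference of genes that fell went from -0.12 to -0.06. Genes that fell had a median GC content of 54.2%, against 47.6% for all genes, which keeps the trend open for them. A biological effect of CD9 on the response remains open and untested.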

How the results depend on the processing

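The pseudocounts and robust option in the tests, the GC and length correction, the restriction to whole reads and the slopes on subsets of genes were chosen after seeing the data. The planned DESeq2 and legacy quasi-likelihood fits were not run, because the deposited values were CPM with divided reads. The main fit pairs dexamethasone with DMSO by line and gives a common treatment effect over both lines, with no test within a line. No further paired analysis was possible because each group held 1 library. For dexamethasone, scaling, filters, voom, pseudocounts, moderation and the GC correction gave 1939 to 2214 genes against 2062. Without the line term 747 passed, and leaving out 1 library (also without that term) gave 524 to 2488. For line, the same settings gave 277 to 462 against 340, the model without treatment 1, and leaving out 1 library 1 to 2. At an unadjusted p under 0.05, the line model without treatment had 406 genes. These fits have fewer terms or libraries, and what remained then holds the omitted factor.

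Under the rule of size, a minimum of 20 reads gave 371 genes for dexamethasone in the GFP line, 459 in the CD9 line, 163 for line in DMSO, 166 for line with dexamethasone and 327 for the response difference. A minimum of 500 reads gave 62, 67, 1, 4 and 1, and a log2 limit of 0.5 gave 565, 803, 146, 306 and 384, as looser or stricter limits must. Restriction to whole reads left 12 genes for the response difference. The slope was 1.23 over all genes, 1.16 over genes with 500 reads, 1.051 over genes called higher and 1.069 over genes called lower, and the cause was not tested. Of 196 gene results followed through 2347 alternatives, 8 changed direction, all on leaving out 1 library without the second factor. For dexamethasone these were CD74 (0.0454), MT-CO1 (0.0841), MT-ND4 (0.11), MT-ND5 (0.13) and H2AC6 (0.0058), and for line SPRY4 (0.30), HSPB1 (0.0798) and NRP1 (0.62). The omitted factor enters these by construction. Without the second factor 111 of the 196 no longer passed, and after the GC correction 7. In the fit with 1 library left out that gave the weakest ratio, more of the 196 lost their call than kept it, besides the 8 that changed direction. CD9 passed under every alternative run. Of 174 list medians under other scalings or pseudocounts, 2 changed sign. Depth of 12197353 to 14794169 reads limits single-library ratios of genes near 100 reads.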

Other observations

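Counts for dexamethasone in other fixed lists are given here, to be read beside 923 higher and 1139 lower among all 14592 tested genes. Among p53 targets 5 of 22 rose and 1 fell (5 and 2 adjusted over the list alone), with AEN, a nuclease, at a log2 of 0.73, BTG2, an antiproliferative gene, at 0.64, SESN1 at 0.47 and CDKN1A, a cell cycle inhibitor, at -0.48. Autophagy and lysosome genes rose for 4 of 26 and fell for 2 (5 and 2 adjusted over the list alone), with WIPI1 at a log2 of 0.97 and CTSB, cathepsin B, at 0.79, and TFEB at a log2 of -0.58. Genes of the unfolded protein and integrated stress responses fell for 9 of 26 and rose for 1 (10 and 1 adjusted over the list alone), with WARS1 at -0.32 and PHGDH at -0.28. Of 25 immediate early genes 2 rose and 5 fell (2 and 7 adjusted over the list alone): SPRY4, a feedback inhibitor of growth factor signalling, rose 2.06-fold and FOSL2, with shared reads, 1.81-fold, while IER2 stood at -0.51. G1/S genes rose for 3 of 34 and fell for 1 (3 and 1 adjusted over the list alone). Mitotic genes fell for 6 of 32 (6 adjusted over the list alone), with PTTG1 at -0.31, and MYC and ribosome biogenesis genes for 4 of 36 (4 adjusted over the list alone), with MYC at -0.20. MYC did not pass without the line term.

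Among class II genes and in the lists on RNA content more members fell than rose with dexamethasone. CIITA, the class II transactivator, rose by a log2 of 0.40, and 3 of 15 class II genes fell (4 lower and 1 higher adjusted over the list alone). Of 56 ribosomal protein genes 12 fell and 4 rose (16 and 4), of 22 histones 7 fell and 1 rose (9 and 1), and of 13 mitochondrial genes 3 fell (7 and 1 higher), the bracketed counts being adjusted over the list alone. In the CD9 line the median log2 ratio was -0.13 for ribosomal protein genes (0th percentile of matched lists), -0.15 for histones (0.17th) and -0.21 for mitochondrial genes (0.12th). In the GFP line these medians were 0.01 (66.9th), -0.0044 (39.6th) and -0.02 (28.65th), and the difference was not tested. The 3 mitochondrial calls did not pass without the line term.

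Between lines, the median log2 difference of further lists lay at the low end of matched lists: -0.18 for heat stress genes and -0.08 for receptor machinery (both at the 0.04th percentile), -0.04 for ribosomal protein genes (0.15th, but 0.0048 and the 55.8th in DMSO alone), -0.06 for mitotic genes (0.39th), -0.07 for glycolysis (0.605th) and -0.11 for class II genes (1.54th). Lower in the CD9 line were 4 of 32 mitotic genes (9 adjusted over the list alone), 3 of 36 receptor machinery genes (5), 2 of 15 class II genes (2), 2 of 9 heat stress genes (2), 2 of 25 glycolysis genes (4), 2 of 32 KMT2A-related genes (2), 1 of 26 interferon genes (1) and 1 of 14 CD9 partner genes (1). Ribosomal protein genes were lower for 7 of 56 and higher for 3 (17 and 7). Immediate early genes were lower for 3 of 25 and higher for 1 (3 and 1), and stress response genes were higher for 2 of 26 (2 higher and 1 lower). No member passed over all genes for the glucocorticoid-induced, BCL2, tetraspanin, B-cell precursor, MYC, cholesterol, G1/S, p53, NF-κB and autophagy lists. Of these, tetraspanins had 1 higher and B-cell precursor genes 1 higher and 3 lower when adjusted over the list alone. In both lists the higher gene was CD9 itself. Median differences between lines were not recomputed for the lists after removal of the GC trend.

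Most markers of other blood and tissue cells did not pass the filter. The highest of those that did were CEBPA at 124 CPM, then PDGFRB, and ZAP70 at 44.0 CPM in the GFP DMSO library. Of 15 T-cell markers 3 were measurable, and LCK, also a kinase of B-lineage leukemia cells, fell by a log2 of 0.63 with dexamethasone (2 lower adjusted over the list alone). Of 14 myeloid markers 4 were measurable and 3 fell (3 adjusted over the list alone): CSF1R, CEBPA at -0.54 and LYZ at -0.77, the last lost without the line term. Of 10 epithelial and stromal markers 3 were measurable, and PDGFRB fell by 0.96 (1 higher and 1 lower adjusted over the list alone). None of the 2 natural killer and 2 mature B or plasma cell markers passed, and no erythroid or megakaryocytic marker passed the filter. Summed levels of the myeloid markers were 147 and 99.9 CPM in the GFP line and 144 and 89.6 CPM in the CD9 line. Between lines no marker passed over all genes, and 1 stromal marker was lower when adjusted over its list alone.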
